A study of Homo sapiens with 16 samples.

How the data were processed

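RNA sequencing was read from gene tables of NCI-H1975 lung adenocarcinoma cells (control, magnolin and chloroform fraction of Flos Magnoliae, 4 libraries each) and of parental HCC827 lung adenocarcinoma cells (2 libraries). Per the labels' protocols, total RNA was extracted, its quality was checked on an Agilent instrument and libraries were made with NEB reagents; strandedness, aligner and counter are not given in the sources used here. The authors deposited FPKM per gene (reads per kilobase of gene, scaled to a library size), and hg38 is the build per the submitters' processing notes. NCI-H1975 replicates 1 and 2 of every group stand together (set A), as do replicates 3 and 4 (set B), and HCC827 stands apart. The 3 sets of values were normalized separately, so tests were made within a set, except in joint fits that hold a term for each replicate number or for the set. In the HCC827 set, 2 columns have names that match no sample label and were not used, so resistant HCC827 cells were not analysed here.

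All 58735 gene identifiers and coordinates matched GENCODE release 29. Multiplying FPKM by gene length gave whole multiples of 1 read for genes of up to 2000 reads, within a tolerance of 0.05, so reads per library were rebuilt. These came to 18.4 to 21.3 M reads in set A, 16.0 to 17.0 M in set B and 15.9 to 16.4 M in HCC827. The library size implied by FPKM was 0.988 to 1.021 times the rebuilt reads in NCI-H1975 and 1.039 to 1.057 times in HCC827. In some libraries it was thus below the rebuilt reads, and how it was set is not known. The rebuilt reads were used for depth, shares of reads, the comparison of library pairs, reads on short genes and an alternative test, but not for the main tests. Precision for low and short genes is limited by counting error at this depth, and genes that share reads with near-identical copies are uncertain because the counting rule is not known. Reads of overlapping or antisense genes cannot be told apart without the strand setting. No pair of libraries agreed within sampling noise: the smallest chi-square per gene over all pairs was 3.92, for control replicates 3 and 4. Within groups of set B it was 3.92 for control, 3.99 for magnolin and 13.06 for the fraction. Within groups of set A it was 127.2, 115.2 and 120.3 in that order, so replicates lay much closer together in set B.

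Values were computed as log2(FPKM + 1), so fold changes are on that scale and understate changes of low genes. Genes with FPKM of at least 1 in at least 2 libraries of a set were tested with limma 3.58.1 (linear model, empirical Bayes with a mean trend) in R 4.3.3, the 3 NCI-H1975 groups sharing 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In this way magnolin and the chloroform fraction were each compared with control, and with each other. Then 37 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 3 measured members, beside camera with an estimated correlation and fry; 716 of 729 list entries matched a gene. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

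Genes were named by rule: the 8 largest rises and 8 largest falls among called protein-coding genes with mean FPKM of at least 2 in the higher group and no overlap between libraries, up to 4 called members of each list, and EGFR, ERBB2, ERBB3, MET, AXL and IGF1R always. In set A, where no gene was called without a block, the rule was applied to the fit with the replicate number as a block, and values from that fit are named as such. Genes named outside the rule are said to be chosen after their values were seen. Of the genes that the rule names, 1 is not reported here.

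Replicate numbers are shared by the groups. Deviations from the group means over all 4 replicates correlated at 0.302 to 0.859 for the 12 pairs with the same number, and in 9 of these 12 pairs the library of the first group correlated best with the same number in the second group, so the numbers were treated as pairing the libraries; the pairing comes from this check alone, since the labels give only numbers. All pairs that correlated best with another number were of replicates 3 and 4. Within set A the 6 correlations were 0.717 to 0.760, and the same number was best in all 6. Within set B they were -0.032 to 0.078, and the same number was best in 2 of 6. With 2 libraries per group the deviations mirror each other, so each of these values stands for both numbers of a set. For set B the check thus gave no sign of pairing by number. Blocked values are given where they change a call or a count by over 1.5 times.

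Tested on simulated data for magnolin versus control with 200 changed genes in each of 10 draws, the set A fit without a block (12695 to 12741 genes) recovered 0.924% of 2-fold and 32% of 4-fold changes, with 5.26% false calls. With the replicate block (12643 to 12678 genes) it recovered 59% and 95%, with 14.3% false calls, of which 85.8% were genes under 300 bases. The set B fit without a block (14096 to 14137 genes) recovered 63.6% and 85.2%, with 6.54% false calls. Simulated reads took limma's moderated spread of each gene, with an upper cap, and counting noise was added on top. Genes of few reads may thus vary otherwise than in the data, and the false-call rates may reflect this. Without the block, differences shared by libraries of the same replicate number were drawn as independent noise. With it, a shift between replicates was drawn at a preset size, not taken from the data. The rates may therefore differ from those in set A.

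The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio rescaling of libraries, the replicate block, limma voom on rebuilt reads, protein-coding genes alone, the 2 compared groups alone, and leaving out each library. After the data were seen, joint fits of both sets, the block combined with voom or with protein-coding genes, fits with 1 control per treatment and the test of a difference between the sets were added. Correlations between treatments that share controls were set beside 100 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.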

Results

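Gene expression was measured by RNA sequencing in human lung adenocarcinoma lines. NCI-H1975 carries an activating and a resistance mutation of EGFR, and HCC827 carries an activating EGFR deletion. NCI-H1975 cells were sequenced as controls, after magnolin, a lignan of Flos Magnoliae (the dried flower buds of Magnolia), and after the chloroform fraction of Flos Magnoliae, with 4 libraries per group. Replicates 1 and 2 of each group form set A and replicates 3 and 4 form set B. The rebuilt depth was 16.0 to 21.3 M reads per NCI-H1975 library, and 12106 to 14011 genes reached 1 FPKM. The labels give no dose or exposure time, so the treatments may differ in either. They do not say that replicates were separate cultures, and p-values measure only the spread between these samples, which may be technical. The series asked which genes change as lung cancer cells become resistant to EGFR kinase inhibitors, and which compounds counter such genes.

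In set B, cells given the chloroform fraction had much lower cell division transcripts and higher amino acid stress, hypoxia and xenobiotic response transcripts than controls. Single members passed as counted below, while none of these 4 list calls held with an estimated correlation (adjusted p = 0.159, 0.114, 0.114 and 0.159). Measures of library quality moved with the treatment too, which was not tested. Genes of the mitochondrial genome took 8.17 and 7.04% of the reads with the fraction, against 5.84 and 5.83% in controls, and the 10 genes with most reads took 9.44 and 8.71% against 6.91% in both controls. CCNB1, the cyclin that drives entry into mitosis (ENSG00000134057, hg38 chromosome 5, 69167010 to 69178245), fell from 110 ± 11.5 to 24.9 ± 1.33 FPKM (mean ± SD, n = 2 per group here and below). All 30 tested mitosis genes fell. CYP1A1, a xenobiotic-metabolizing oxidase induced by the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose from 1.30 ± 0.0906 to 21.7 ± 2.20 FPKM. CCL2, a monocyte-attracting chemokine (ENSG00000108691, chromosome 17, 34255218 to 34257203), fell from 16.9 ± 2.88 to 0.215 ± 0.00216 FPKM.

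The mitosis list had a median log2 change of -1.69 in set B (limma camera, adjusted p = 1.23e-26; adjusted p = 0.159 with an estimated correlation), and 30 of 30 members also passed adjusted over the list alone. The kinesin KIF20A fell from 32.1 ± 4.91 to 4.49 ± 0.652 FPKM, DLGAP5 from 26.4 ± 1.46 to 5.60 ± 0.0849, the proliferation marker MKI67 from 40.0 ± 1.96 to 10.3 ± 0.00268, and the kinetochore gene CENPF from 39.6 ± 1.56 to 10.5 ± 0.297. Of 30 S phase genes 27 fell, 29 adjusted over the list alone, with a median of -0.80 (adjusted p = 1.35e-14; adjusted p = 0.232 with an estimated correlation). PCNA, the DNA polymerase clamp, fell from 169 ± 1.46 to 88.3 ± 7.03 FPKM, the helicase subunit MCM7 from 85.3 ± 2.36 to 42.9 ± 4.58 and RRM1, a ribonucleotide reductase subunit, from 48.8 ± 4.27 to 24.3 ± 1.03.

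Of 25 targets of the stress-induced transcription factor ATF4, 23 rose in set B, also 23 adjusted over the list alone, with a median of 1.57 (adjusted p = 2.85e-22; adjusted p = 0.114 with an estimated correlation). CHAC1, which degrades glutathione, rose from 1.47 ± 0.658 to 14 ± 4.11 FPKM, PCK2 from 5.87 ± 0.117 to 36.1 ± 2.46, the serine synthesis gene PHGDH (ENSG00000092621, chromosome 1, 119648411 to 119744226) from 4.30 ± 0.277 to 21.2 ± 0.928 and PSAT1 from 66.9 ± 2.5 to 201 ± 4.58. Among 24 hypoxia and glycolysis genes 16 rose and 1 fell, 17 and 2 adjusted over the list alone, with a median of 0.64 (adjusted p = 1.85e-09; adjusted p = 0.114 with an estimated correlation). NDRG1 rose from 8.44 ± 0.344 to 54.5 ± 1.78 FPKM, VEGFA from 13.6 ± 0.778 to 38.6 ± 1.22 and ANGPTL4 from 39.5 ± 4.39 to 192 ± 37.6. Of 6 aryl hydrocarbon and xenobiotic receptor targets 5 rose, 6 adjusted over the list alone, with a median of 0.93 (adjusted p = 9.86e-06; adjusted p = 0.159 with an estimated correlation). CYP1B1 went from 194 ± 6.55 to 406 ± 35.8 FPKM and TIPARP from 21.3 ± 2.07 to 49.8 ± 6.62. Of 21 NRF2 targets 8 rose and 3 fell, 12 and 4 adjusted over the list alone (median 0.39, adjusted p = 0.000976; adjusted p = 0.273 with an estimated correlation). SLC7A11, the cystine importer, which is also on the ATF4 list, rose from 3.28 ± 0.471 to 16.5 ± 1.90 FPKM.

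With the fraction in set B, 12 of 20 NF-kB and inflammatory genes fell and 2 rose, the same numbers adjusted over the list alone, with a median of -0.77 (adjusted p = 0.00061; adjusted p = 0.232 with an estimated correlation). CXCL1 fell from 34.3 ± 0.607 to 5.13 ± 0.184 FPKM and SOD2, the mitochondrial superoxide dismutase, from 42.3 ± 3.43 to 14.2 ± 1.47. Of 23 interferon-stimulated genes 13 fell, with 14 lower and 1 higher adjusted over the list alone (median -0.60, adjusted p = 2.68e-05; adjusted p = 0.159 with an estimated correlation). OAS3 fell from 20.2 ± 0.238 to 6.53 ± 0.802 FPKM and BST2 from 230 ± 0.493 to 126 ± 1.23. IL7R, a cytokine receptor chain (ENSG00000168685, chromosome 5, 35852695 to 35879603), fell from 16.7 ± 1.46 to 1.69 ± 0.0312 FPKM, and the acute phase gene SAA1 from 26.3 ± 4.07 to 0.998 ± 0.443. SERPINB4 fell from 20.6 ± 0.611 to 1.29 ± 0.420 FPKM and SERPINB3 from 11.1 ± 0.678 to 0.551 ± 0.442, a near-identical pair whose reads may be split. The cytokine IL11 rose from 4.44 ± 0.330 to 27.0 ± 2.86 FPKM, the neuropeptide precursor VGF from 5.66 ± 0.805 to 31.7 ± 8.13 and the stress cytokine GDF15 from 20.8 ± 0.721 to 90.0 ± 19.8.

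Smaller shifts with the fraction in set B took in further lists. Of 18 genes that report ERK activity 10 rose, also 10 adjusted over the list alone (median 0.34, adjusted p = 0.000104; adjusted p = 0.159 with an estimated correlation). Among them were CCND1, from 46.5 ± 2.80 to 87.1 ± 3.42 FPKM, and DUSP6, from 4.12 ± 0.181 to 8.18 ± 0.966. Of 15 heat shock genes 9 fell, 10 adjusted over the list alone (median -0.43, adjusted p = 0.000166; adjusted p = 0.321 with an estimated correlation). Of 29 nuclear respiratory chain genes 11 fell, 14 adjusted over the list alone (median -0.27, adjusted p = 2.68e-05; adjusted p = 0.321 with an estimated correlation). Of 23 cholesterol genes 9 fell, with 11 lower and 1 higher adjusted over the list alone (median -0.22, adjusted p = 0.000566; adjusted p = 0.206 with an estimated correlation). Of 9 replication-dependent histones, a list kept as a sign of RNA quality, 4 rose, 5 adjusted over the list alone (median 0.40, adjusted p = 0.00454; adjusted p = 0.206 with an estimated correlation). Of 20 p53 targets 6 rose, 7 adjusted over the list alone, and the list call (adjusted p = 0.0491; adjusted p = 0.321 with an estimated correlation) was lost with the replicate block (0.0596) and with rescaling (0.0599). CDKN1A, a cyclin-dependent kinase inhibitor, rose from 9.79 ± 0.736 to 26.5 ± 3.10 FPKM. EGFR itself (ENSG00000146648, chromosome 7, 55019021 to 55211628) measured 28.5 ± 0.713 FPKM in controls and 32.6 ± 1.18 with the fraction, which did not pass (adjusted p = 0.123). ERBB2, MET, AXL and IGF1R did not pass either (adjusted p = 0.817, 0.637, 0.233 and 0.103), and ERBB3 was too low in set B to be tested. The ligands AREG, from 6.71 ± 0.985 to 11.9 ± 0.927 FPKM, and TGFA, from 4.70 ± 0.893 to 8.18 ± 0.50, rose. Their list, the EGFR family and its ligands, was not called (limma camera, median 0.16, adjusted p = 0.274).

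Of 14673 genes tested in set B, limma called 1222 higher and 1696 lower with the fraction than in controls, 234 and 310 of them by at least 2-fold. After median-ratio rescaling 1371 were higher and 1471 lower. The total of 2918 became 1598 with no filter on low genes, 947 without control replicate 3 and 728 without control replicate 4. No list call in any comparison of either set held with an estimated correlation.

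In set A, where the libraries of a group lay further apart, fewer genes passed. Limma without a block called 0 of 13103 genes, with 107 at an unadjusted p under 0.05, and limma voom also called 0. With the replicate block 12 genes were higher and 12 lower, of which 5 were protein-coding and 16 shorter than 300 bases. Values of single genes in set A come from the block fit, and list tests and member counts from the fit without a block unless the block is named. Mitochondrial genes took 7.60 and 8.42% of the reads with the fraction and 9.42 and 8.06% in controls. CYP1A1 rose from 2.08 ± 0.591 to 12.2 ± 4.92 FPKM (log2 change 2.07, SE 0.23, adjusted p = 0.00104), ANGPTL4 from 30.4 ± 1.33 to 73.8 ± 13.9, CYSRT1 from 1.32 ± 0.295 to 4.04 ± 1.19 and the metalloprotease ADAM8 from 5.62 ± 2.51 to 13.8 ± 8.15. EGFR measured 25.7 ± 15.6 FPKM in controls and 29.2 ± 13.7 with the fraction, and neither it nor ERBB2, ERBB3, MET, AXL or IGF1R passed (adjusted p = 1 each). The mitosis list was called lower with a median of -0.28 (adjusted p = 6.82e-06; adjusted p = 0.85 with an estimated correlation) and the S phase list with -0.12 (adjusted p = 0.00889; adjusted p = 0.925 with an estimated correlation). No member of either passed, over all genes or adjusted over the list alone, without the block or with it. ATF4 targets were called higher with a median of 0.20, with no member passing adjusted over the list alone without the block and 2 of 24 with it (adjusted p = 2.35e-05; adjusted p = 0.514 with an estimated correlation). Xenobiotic receptor targets were called higher with 0.46 and 1 of 7 passing adjusted over the list alone, or 3 with the block, where CYP1A1 also passed over all genes (adjusted p = 0.00085; adjusted p = 0.514 with an estimated correlation). In all, 8 lists were called, against 3 without fraction replicate 2, 14 without control replicate 1 and 4 with no filter.

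In a fit of both sets with the replicate block, limma called 19 genes higher and 6 lower with the fraction, of 13614 tested, and its rank order was led by IL11 (log2 change 2.12, SE 0.174, adjusted p = 0.00359) and CYP1A1 (2.68, SE 0.282, adjusted p = 0.0115). CYP1B1, ANGPTL4, VGF, ADAM8 and DUSP6 were also higher, and CXCL2, SOD2 and CP lower. The 25 calls became 107 without replicate 1, 0 without replicate 3 (1242 at an unadjusted p under 0.05, 20 by limma voom) and 0 without replicate 4 (1002 and 12). They became 235 with limma voom, 65 with a pseudocount of 0.1 and 1 with a term for the set in place of the block. These genes outside the naming rule were chosen after their values were seen.

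**Figure D1:**
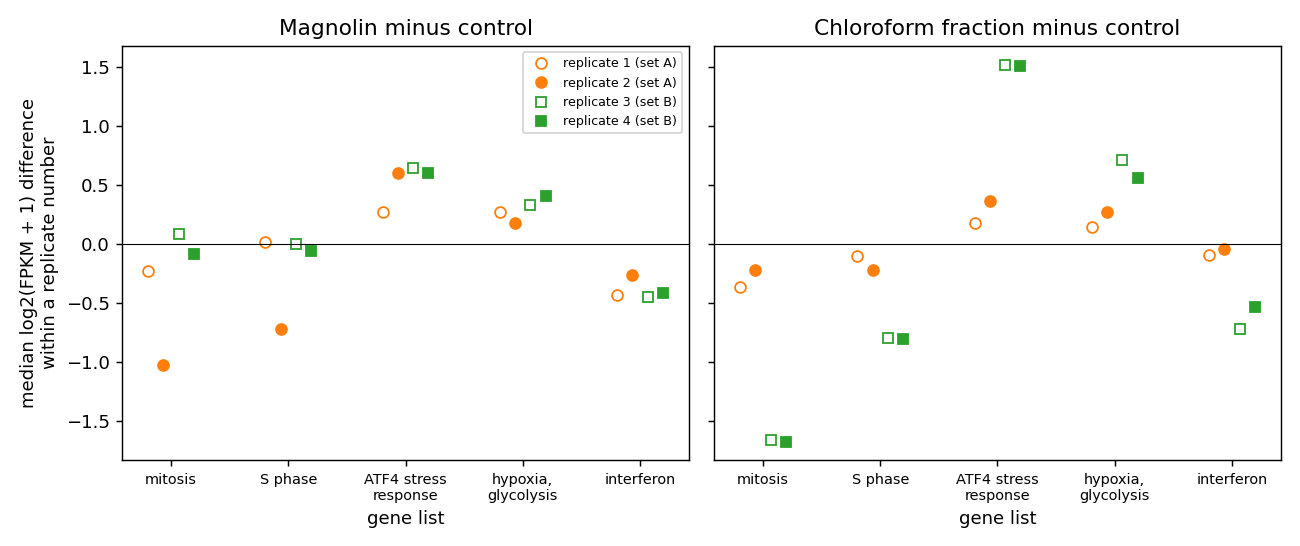
Median log2(FPKM + 1) difference from the control of the same replicate number for 5 gene lists, magnolin on the left and the chloroform fraction on the right, with 1 point per replicate (orange circles set A, green squares set B). With the fraction the mitosis medians were -0.36 and -0.22 in replicates 1 and 2 and -1.66 and -1.67 in replicates 3 and 4; with magnolin they were -0.23, -1.02, 0.09 and -0.08.

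Magnolin was compared with control to ask what this single constituent changes. In set B 92 genes were called, among them 7 higher ATF4 targets and 5 lower epithelial markers, while mitosis genes had a median change of 0.02 (adjusted p = 0.716). Mitochondrial genes took 6.40 and 6.38% of the reads with magnolin and the 10 genes with most reads 7.55 and 7.54%, both above the controls. PHGDH rose from 4.30 ± 0.277 to 12.5 ± 0.341 FPKM (log2 change 1.35, SE 0.081, adjusted p = 0.0182), the amino acid transporter SLC7A5 from 115 ± 9.76 to 265 ± 5.14 and NDRG1 from 8.44 ± 0.344 to 22.9 ± 0.578. CCL2 fell from 16.9 ± 2.88 to 3.62 ± 0.127 FPKM and the death ligand gene TNFSF10 from 7.73 ± 0.654 to 1.05 ± 0.309.

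Of 25 ATF4 targets 7 rose with magnolin in set B, 19 adjusted over the list alone, with a median of 0.59 (adjusted p = 1.80e-19; adjusted p = 0.0775 with an estimated correlation). PCK2 rose from 5.87 ± 0.117 to 14.1 ± 1.36 FPKM and PSAT1 from 66.9 ± 2.5 to 123 ± 2.56. Of 24 hypoxia and glycolysis genes 2 rose, 18 adjusted over the list alone (median 0.39, adjusted p = 9.57e-15; adjusted p = 0.0775 with an estimated correlation). Of 6 xenobiotic receptor targets 3 rose, 6 adjusted over the list alone (median 0.61, adjusted p = 6.11e-08; adjusted p = 0.105 with an estimated correlation). CYP1A1 rose from 1.30 ± 0.0906 to 8.64 ± 3.12 FPKM, and CYP1B1 from 194 ± 6.55 to 340 ± 14.2, the latter not with the replicate block (adjusted p = 0.0605). Of 20 epithelial markers 5 fell, 15 adjusted over the list alone (median -0.45, adjusted p = 4.44e-14; adjusted p = 0.078 with an estimated correlation). The mucin MUC1 fell from 20.8 ± 2.21 to 9.47 ± 0.941 FPKM. KRT8 and CDH3 fell without the block but not with it (adjusted p = 0.0759 each). The mesenchymal list was also called lower, not higher (limma camera, median -0.13, adjusted p = 0.0311), a call that did not hold with an estimated correlation. Of 23 interferon-stimulated genes none passed over all genes and 11 were lower adjusted over the list alone (median -0.43, adjusted p = 6.04e-08; adjusted p = 0.078 with an estimated correlation). Of 20 NF-kB and inflammatory genes 1 fell, with 10 lower and 3 higher adjusted over the list alone (median -0.31, adjusted p = 0.000858; adjusted p = 0.248 with an estimated correlation). Histones had a median of 0.34 with 4 of 9 higher adjusted over the list alone (adjusted p = 0.000858; adjusted p = 0.156 with an estimated correlation).

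Among single genes in set B, magnolin raised the cytokines IL24, from 6.25 ± 0.815 to 17.7 ± 2.68 FPKM, and IL11, from 4.44 ± 0.330 to 13 ± 1.90, the metallothionein MT1A, from 6.49 ± 1.10 to 17.8 ± 3.20, and the matrix gene FBLN1, from 3.58 ± 0.297 to 9.61 ± 0.951. S100A9 fell from 35.5 ± 10.2 to 7.22 ± 2.21 FPKM, ZBED6CL from 13.3 ± 3.32 to 3.23 ± 0.143, SEMA6B from 6.93 ± 0.852 to 1.53 ± 0.212 and SERPINB4 from 20.6 ± 0.611 to 6.32 ± 1.04. CD14 fell from 26.7 ± 8.24 to 6.26 ± 0.20 FPKM and the chemokine CXCL6 from 4.86 ± 0.437 to 1.01 ± 0.253, but neither passed with the block (adjusted p = 0.0603 and 0.0568). MT1A and S100A9 belong to families of similar genes. EGFR measured 28.5 ± 0.713 FPKM in controls and 25.3 ± 0.808 with magnolin and did not pass (adjusted p = 0.366), nor did ERBB2, MET, AXL and IGF1R (adjusted p = 0.613, 0.59, 0.996 and 0.972).

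Limma called 37 genes higher and 55 lower with magnolin in set B, 15 and 28 of them by at least 2-fold, and with the replicate block 21 and 22. The 92 calls became 0 without control replicate 3, control replicate 4, magnolin replicate 3 or magnolin replicate 4 (1063, 1322, 1484 and 1188 at an unadjusted p under 0.05; 133, 207, 218 and 163 by limma voom). They became 154 without fraction replicate 3, 140 without fraction replicate 4, 578 with limma voom on all libraries, 395 among protein-coding genes, 218 among genes with a mean FPKM of at least 5, and 165 with the 2 groups alone. They became 0 with no filter (3021 at an unadjusted p under 0.05, 360 by limma voom).

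In set A without a block limma called 0 of 13103 genes, with 255 at an unadjusted p under 0.05, and limma voom called 0. With the replicate block 63 were higher and 67 lower. IL7R fell from 15.6 ± 0.187 to 3.34 ± 0.602 FPKM (log2 change -1.94, SE 0.18, adjusted p = 0.000281), and CHAC1 rose from 1.39 ± 0.874 to 6.47 ± 0.644 (1.69, SE 0.21, adjusted p = 0.00404). The immediate early genes EGR1, from 14.3 ± 0.978 to 52.1 ± 31.9 FPKM, and FOS, from 2.07 ± 1.04 to 6.35 ± 1.36, rose, as did DDIT4, ANGPTL4, PHGDH and HMOX1, which degrades haem (22.5 ± 8.95 to 48.9 ± 23.8). TM4SF1 fell from 56.3 ± 22.1 to 28.3 ± 16.1 FPKM, CXCL1 from 48.0 ± 43.2 to 17.8 ± 15.3, and CT45A2, of a family of near-identical copies, from 14.7 ± 7.73 to 5.33 ± 4.12.

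With magnolin in set A 10 lists were called. The mitosis list was lower (median -0.62, adjusted p = 5.95e-14; adjusted p = 0.57 with an estimated correlation). So was the S phase list (median -0.34, adjusted p = 4.50e-07; adjusted p = 0.57 with an estimated correlation). Against the control of the same number, the S phase median was 0.02 in replicate 1 and -0.72 in replicate 2. The mitosis median was -0.23 and -1.02. Without the block no member of either passed, over all genes or adjusted over the list alone. With it 17 of 30 mitosis genes were lower adjusted over the list alone and 0 over all genes, and of 30 S phase genes POLE2 alone was lower in both ways. ATF4 targets were called higher with a median of 0.44, 2 of 24 adjusted over the list alone, while with the block 5 rose, 12 adjusted over the list alone (adjusted p = 7.61e-09; adjusted p = 0.532 with an estimated correlation). NRF2 targets had a median of 0.44, and none passed adjusted over the list alone without the block, while with it HMOX1 rose and 6 of 20 were higher adjusted over the list alone (adjusted p = 0.000129; adjusted p = 0.532 with an estimated correlation). Histones had a median of 0.60, again with none passing adjusted over the list alone without the block, while with it HIST1H2BD and HIST1H2BC rose and 7 of 10 were higher adjusted over the list alone (adjusted p = 0.000567; adjusted p = 0.57 with an estimated correlation). In the other 5 called lists no member passed without the block, over all genes or adjusted over the list alone. Their medians were -0.38 for interferon-stimulated genes, 0.28 for hypoxia and glycolysis, -0.22 for ribosome biogenesis, 0.31 for FOXO targets and 0.21 for p53 targets (adjusted p = 0.000567, 0.00116, 0.00746, 0.0222 and 0.0234; adjusted p = 0.57, 0.532, 0.57, 0.57 and 0.532 with an estimated correlation). With the block ANGPTL4 and ALDOA of 24 hypoxia and glycolysis genes rose over all genes, and 3 adjusted over the list alone. In the block fit no member of the other 4 passed over all genes. Adjusted over the list alone, 5 of 23 interferon-stimulated genes were lower, 1 of 13 FOXO targets and 3 of 20 p53 targets higher, and 0 of 22 ribosome biogenesis genes passed. NF-kB and inflammatory genes were not called as deposited (adjusted p = 0.0562), but passed after rescaling (0.0476) and with the replicate block (0.000549), where 4 of 22 fell, 7 adjusted over the list alone (adjusted p = 0.591 with an estimated correlation). In the block fit ERBB2 measured 3.98 ± 0.852 FPKM in set A controls and 7.09 ± 0.607 with magnolin and did not pass (adjusted p = 0.089), nor did EGFR, ERBB3, MET, AXL and IGF1R (adjusted p = 0.929, 0.702, 0.861, 0.229 and 0.635). In the fit of both sets limma called 0 genes for magnolin, with 1302 at an unadjusted p under 0.05 and 24 by limma voom. Between the sets, 5 genes rose and 7 fell with magnolin in both lists of calls (set A with the block, set B without), against 0.175 and 0.247 for independent lists. PHGDH, PCK2, IL11, DHRS2 and LZTS3 rose, and IL7R, CCL2, SERPINB4, TM4SF1, BMP4, COL8A1 and the short mitochondrial tRNA gene MT-TF fell, a grouping chosen after its values were seen. For the fraction 5 genes rose in both lists of calls against 0.874 for independent lists, namely CYP1A1, IL11, ANGPTL4, ADAM8 and CYSRT1. None fell in both against 1.32, and RNU7-75P, a pseudogene of a small nuclear RNA, rose in set A and fell in set B.

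**Figure D2:**
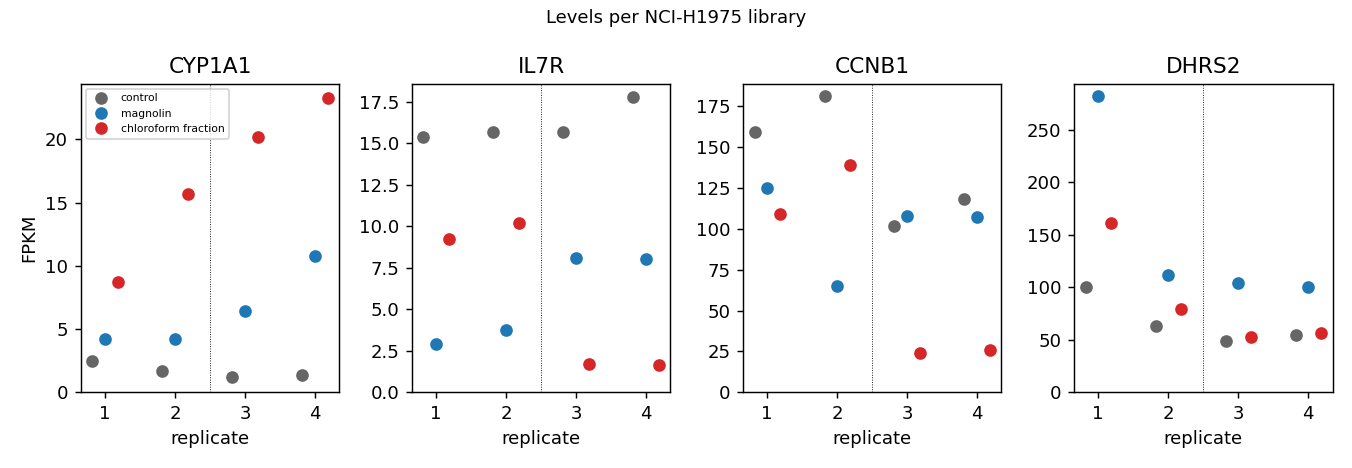
FPKM of CYP1A1, IL7R, CCNB1 and DHRS2 in each NCI-H1975 library by replicate number and treatment, on linear axes, with a dotted line between set A and set B, which were normalized separately. CCNB1 with the fraction was 109 and 139 FPKM in replicates 1 and 2, and 24.0 and 25.9 in replicates 3 and 4; DHRS2 with magnolin was 282, 112, 104 and 100 FPKM.

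The chloroform fraction was then set directly against magnolin, at doses and times the labels do not give. In set B, mitochondrial genes took 6.40 and 6.38% of the reads with magnolin and 8.17 and 7.04% with the fraction. CCNB1 was 107 ± 0.605 FPKM with magnolin and 24.9 ± 1.33 with the fraction (log2 change -2.07, SE 0.091, adjusted p = 0.000716), and KIF20A was 28.7 ± 0.217 and 4.49 ± 0.652. CYP1A1 was also higher with the fraction than with magnolin, 21.7 ± 2.20 against 8.64 ± 3.12 FPKM (adjusted p = 0.0183). All 30 mitosis genes were lower, also adjusted over the list alone (median -1.68, adjusted p = 1.24e-29; adjusted p = 0.262 with an estimated correlation). So were 28 of 30 S phase genes, 29 adjusted over the list alone (median -0.74, adjusted p = 1.42e-16; adjusted p = 0.262 with an estimated correlation). The topoisomerase TOP2A was 83.5 ± 0.782 and 21.8 ± 0.139 FPKM, ANLN 105 ± 2.23 and 27.4 ± 0.966, and HMMR 20.9 ± 0.0704 and 4.89 ± 0.148. Of 25 ATF4 targets 22 were higher, 23 adjusted over the list alone (median 0.73, adjusted p = 2.08e-17; adjusted p = 0.187 with an estimated correlation). The stress factor DDIT3 was 6.48 ± 0.308 with magnolin and 20 ± 1.65 FPKM with the fraction, TRIB3 39.7 ± 3.02 and 101 ± 10.3, SESN2 5.57 ± 0.0847 and 18.3 ± 1.23, and GDF15 30.3 ± 3.0 and 90.0 ± 19.8. KLHDC7B was 1.72 ± 0.684 and 15.1 ± 1.37 FPKM. Of 15 heat shock genes 9 were lower, 11 adjusted over the list alone (median -0.46, adjusted p = 2.71e-05; adjusted p = 0.262 with an estimated correlation). Of 20 NF-kB and inflammatory genes 10 were lower, with 11 lower and 1 higher adjusted over the list alone (median -0.45, adjusted p = 0.0021; adjusted p = 0.262 with an estimated correlation). EGFR was higher with the fraction than with magnolin, 32.6 ± 1.18 against 25.3 ± 0.808 FPKM (adjusted p = 0.0283), but not with the replicate block (adjusted p = 0.0596). ERBB2, MET, AXL and IGF1R did not pass (adjusted p = 0.556, 0.196, 0.236 and 0.124).

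Of 14673 genes in set B, limma called 814 higher and 1374 lower with the fraction than with magnolin, and 471 and 840 with the replicate block. Higher calls made up 37.2% of the total as deposited and 50.6% after median-ratio rescaling of the libraries, under which the call of lower ribosomal protein genes was also lost (adjusted p = 0.0183 as deposited, 0.0582 rescaled; adjusted p = 0.589 with an estimated correlation; 3 of 30 lower, 0 adjusted over the list alone). The 2188 calls became 294 without magnolin replicate 3, 226 without magnolin replicate 4, 951 without control replicate 3, 937 without control replicate 4, 752 with no filter, 1034 with the 2 groups alone and 3524 with limma voom.

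In set A the direction of the cell cycle lists was the opposite. Mitosis genes were called higher with the fraction than with magnolin (median 0.35, adjusted p = 1.47e-08; adjusted p = 0.564 with an estimated correlation). S phase genes were too (median 0.21, adjusted p = 3.94e-05; adjusted p = 0.595 with an estimated correlation), no member of either passing over all genes or adjusted over the list alone, without the block or with it. Both medians turned without magnolin replicate 2, to -0.09 and -0.13. In the same comparison replication-dependent histones, the list kept as a sign of RNA quality, were called lower with the fraction (median -0.57, adjusted p = 1.24e-05; adjusted p = 0.564 with an estimated correlation), with none of 10 passing over all genes and 1 lower adjusted over the list alone. With the block HIST1H2BC was lower over all genes and 7 were lower adjusted over the list alone. ATF4 targets were called lower (median -0.23, no member passing adjusted over the list alone without the block and 3 lower with it, adjusted p = 0.000154; adjusted p = 0.564 with an estimated correlation), but their median was 0.00 without magnolin replicate 2 and 0.01 without fraction replicate 1. Without a block limma called 0 of 13103 genes (93 at an unadjusted p under 0.05, 0 by limma voom), and with it 15 higher and 9 lower. IL24 was 11.3 ± 0.134 FPKM with magnolin and 44.5 ± 7.03 with the fraction, IL7R 3.34 ± 0.602 and 9.72 ± 0.729, CYP1A1 4.19 ± 0.0254 and 12.2 ± 4.92, and EGR1 52.1 ± 31.9 and 19.0 ± 8.24. EGFR, ERBB2, ERBB3, MET, AXL and IGF1R did not pass (adjusted p = 1, 0.655, 1, 1, 0.506 and 1). In the fit of both sets limma called 0 genes, with 997 at an unadjusted p under 0.05 and 13 by limma voom.

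The difference between the sets was itself tested, with the replicate block, for 13614 genes. For the fraction against control 19 genes had a higher and 37 a lower change in set B than in set A. These included IL7R, with a difference of -2.09 (SE 0.17, adjusted p = 0.0132), MKI67, with -1.70, CXCL1, with -2.25, PCK2, with 1.90, and PHGDH, with 1.60. The mitosis list differed by a median of -1.41 (adjusted p = 1.80e-27; adjusted p = 0.255 with an estimated correlation) and ATF4 targets by 1.20 (adjusted p = 1.30e-26; adjusted p = 0.0773 with an estimated correlation). The RNA quality list of histones also differed, by 0.46 (adjusted p = 0.0149; adjusted p = 0.255 with an estimated correlation), and the 4 measured fibroblast markers by -0.79 (adjusted p = 0.00766; adjusted p = 0.255 with an estimated correlation). For magnolin against control limma called 0 genes as different, with 1718 at an unadjusted p under 0.05, and the mitosis list differed by 0.59 (adjusted p = 8.49e-09; adjusted p = 0.661 with an estimated correlation). Histones differed by -0.42 (adjusted p = 0.0248; adjusted p = 0.565 with an estimated correlation). For the fraction against magnolin 120 genes had a higher and 199 a lower change in set B, and the mitosis list differed by -2.01 (adjusted p = 1.41e-28; adjusted p = 0.274 with an estimated correlation). There histones differed by 0.74 (adjusted p = 0.000153; adjusted p = 0.191 with an estimated correlation) and fibroblast markers by -0.79 (adjusted p = 0.00545; adjusted p = 0.275 with an estimated correlation). Across 12539 genes, which are not independent replicates, log2 changes in the sets correlated at 0.138 for magnolin, 0.412 for the fraction and -0.213 for the fraction against magnolin. Among genes called in set B for the same comparison these correlations were 0.778, 0.673 and -0.399. Of these called genes 86, 80.7 and 27.9% had the same sign in set A, against 49.8, 65 and 41.1% of all genes.

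The magnolin and fraction responses were compared across genes to ask how far the single constituent and the fraction move the same genes. In set B the log2 changes correlated at a Pearson r of 0.478 (Spearman rho 0.402), against 0.50 simulated for unchanged groups with the same controls. The covariance was 0.0705 against 0.0226 simulated, a difference of 0.0479. In set A r was 0.648 (rho 0.677) against 0.499 simulated, with covariances of 0.0536 and 0.0217 and a difference of 0.0319. That r was 0.357 without fraction replicate 1, 0.392 without fraction replicate 2 and 0.404 without magnolin replicate 1, and no simulated value was made for these. With a different control for each treatment r was 0.204 and 0.284 in set B and -0.373 and -0.271 in set A. This puts the difference between the controls, large between replicates 1 and 2, into the responses with opposite sign and lowers r by construction. Each treatment then rests on 1 control library, and none is shared. In set B the covariances were 0.0373 and 0.0487, which a shared control cannot give. In set A they were -0.0818 and -0.0515 and cannot decide, since the difference between the controls enters them. Of the genes called in set B, 35 were higher and 50 lower with both treatments, and 0 went opposite ways. Independent lists would share 3.08 and 6.36, but these lists share their controls, so the excess is not a measure of shared effect. CYP1A1, NDRG1, PHGDH and IL11 were higher with both, and CCL2, S100A9 and SERPINB4 lower.

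Levels of several epithelial and mesenchymal genes set replicate 1 of NCI-H1975 apart from the other 9 libraries in all 3 groups. EPCAM, an epithelial adhesion molecule (ENSG00000119888, chromosome 2, 47345158 to 47387601), was at 172 to 193 FPKM in the 3 replicate 1 libraries and 7.65 to 14.4 in the other 9, of which the 6 of set B were normalized separately. CDH1 (E-cadherin) was at 54.2 to 74.2 and 4.88 to 9.39 FPKM, KRT7 at 321 to 406 and 46.9 to 71.0, and MET at 84.4 to 116 and 32.8 to 41.7. The lower genes included NNMT, at 2.80 to 5.82 and 51.9 to 113 FPKM, SPARC, at 10.4 to 12.6 and 37.1 to 66.3, and ZEB1, a repressor of epithelial genes, at 1.13 to 1.68 and 2.97 to 4.61. The ranges overlapped for KRT8, at 119 to 134 and 99.6 to 187 FPKM, and KRT18, at 170 to 205 and 94.3 to 174, and for EGFR, ERBB2 and IGF1R. These levels enter every set A mean and, with replicate 1 in each group, every set A spread. In parental HCC827 cells, normalized separately and without a comparison here, EGFR was at 447 and 472 FPKM, against 14.7 to 38.8 in NCI-H1975.

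**Figure D3:**
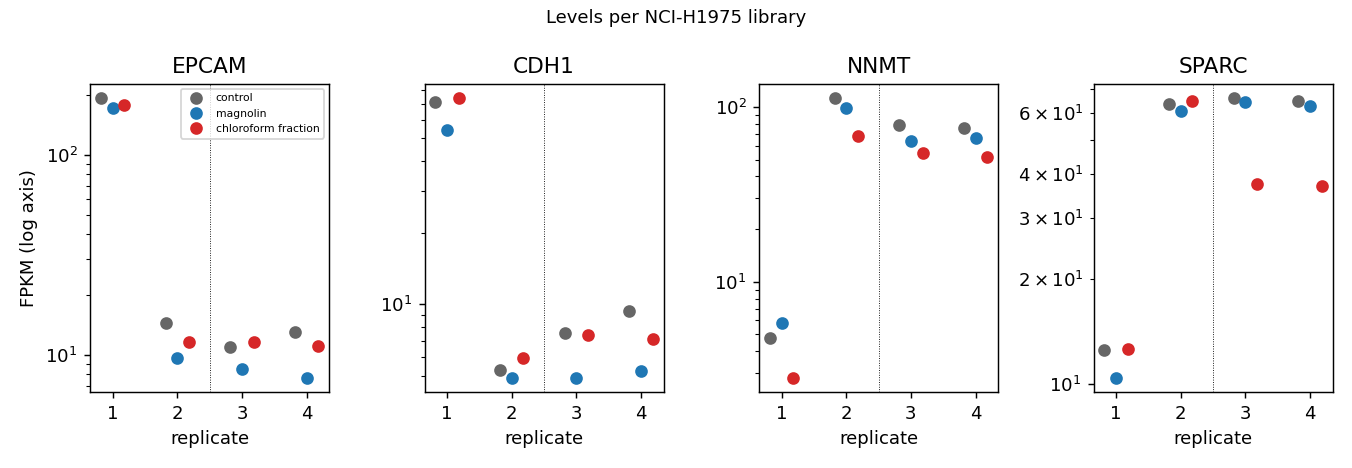
FPKM of EPCAM, CDH1, NNMT and SPARC in each NCI-H1975 library by replicate number and treatment, on log axes, with a dotted line between set A and set B, which were normalized separately. EPCAM was at 172 to 193 FPKM in the 3 replicate 1 libraries and at 7.65 to 14.4 in the other 9, and NNMT at 2.80 to 5.82 and 51.9 to 113.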

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

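In this part the tests of HCC827 RNA, fibroblasts, exchanged labels and magnolin replicate 2, the joint fits of both sets and the tests of a difference between the sets were chosen only after the results were seen.

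Replicate 1 lay far from the other 3 libraries of its group in the mean level of epithelial markers and in ERBB3 and MET. The mean log2 level of the epithelial list in replicate 1 was 4.97 in control, 4.88 with magnolin and 5.06 with the fraction. ERBB3 was at 2.53, 3.51 and 3.29 FPKM, MET at 116, 86.0 and 84.4 FPKM, and AXL in control at 23.8 FPKM. In magnolin replicate 1 the mean log2 level was 3.29 for interferon-stimulated genes and 3.34 for mesenchymal markers, also far from the other 3. Of 54 groups of 4 values examined, 12 held such a library, in each case replicate 1. Chance alone sets a library this far apart in about 1 in 20 groups, but these groups are related measures on the same 12 libraries, so the count cannot be weighed against that share. Replicates 1 and 2 were normalized separately from replicates 3 and 4.

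The values argue against HCC827 RNA as most of replicate 1: over 18 genes high in HCC827 and under 1 FPKM in the other 9 libraries, the median was at most 0.141% of the HCC827 level, normalized separately. They argue against fibroblasts as most of the other 9 libraries, where COL3A1, DCN and LUM reached at most 0.197 FPKM. They argue against library scaling, since the median over all genes of replicate 1 minus replicate 2 was at most 0.011 in size, while the epithelial list had medians of 1.98, 2.0 and 2.20. No biological explanation was tested, as the labels give no group for it. A different subline, another culture state or RNA of a line not examined here may underlie replicate 1, which these data hold no test of.

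Mitosis genes fell with the fraction in set B (median -1.69; adjusted p = 0.159 with an estimated correlation) and were called lower as a list with magnolin in set A (median -0.62; adjusted p = 0.57 with an estimated correlation). Exchanged magnolin and fraction labels in 1 set cannot be told apart from a real difference: unlike treatments correlated between the sets at 0.484 and 0.119 across genes and like ones at 0.138 and 0.412, so the sums favor an exchange by 0.053, but CYP1A1 and HIST1H2BC differed between the treatments in the same direction in both sets and 4 genes, IL7R among them, in opposite directions. With set A taken by replicate, unlike treatments correlated at 0.243 and -0.055 in replicate 1 and like ones at 0.069 and 0.238. In replicate 2 unlike treatments correlated at 0.516 and 0.262 and like ones at 0.147 and 0.381. The sums thus leaned to an exchange in replicate 2 and against it in replicate 1. Against an exchange, DHRS2 was higher with magnolin than with the fraction in all 4 replicates, but in set A this did not pass (adjusted p = 0.466 with the block). A magnolin effect in replicate 2 alone cannot be told apart either: the median was -0.23 in replicate 1, with 25 of 30 genes lower, and -1.02 in replicate 2, with 30 of 30 lower. Doses and times, not given by the labels, might differ between the sets and were not tested.

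The response to the fraction differed between the sets for 56 genes and 15 lists, that to magnolin for 10 lists, and the contrast of the fraction with magnolin for 319 genes and 16 lists. With an estimated correlation limma's camera called 0 of these lists.

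For the fraction against control in both sets, the real grouping of the 8 libraries called 25 genes and the highest of the other splits called 0. Thus 1 of 35 splits gave as many. The remaining splits, apart from 7, put both libraries of some replicate pair on the same side, which the block treats differently. Among the 7 that part every pair the highest count was also 0, and with the real grouping these are too few for a share under 0.05. The count was 0 without replicate 3 or without replicate 4 (limma; 1242 and 1002 genes at an unadjusted p under 0.05, 20 and 12 by limma voom) and 1 with a term for the set. For magnolin against control all 35 splits gave at least the real count of 0 (limma; 1302 genes at an unadjusted p under 0.05, 24 by limma voom), with 17 at the highest and 0 among the 7 that part every pair. For the fraction against magnolin all 35 gave at least the real count of 0 (limma; 997 and 13), with 30 at the highest and 6 among the 7 that part every pair. A real count of 0 is matched by every split by construction, so these say nothing about chance. The splits with 17 and 30 calls left some pair on the same side. They may point to a structure of the samples by set or replicate, and what gave these counts was not tested.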

How the results depend on the processing

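The joint fits, the block combined with voom or protein-coding genes, the fits with 1 control per treatment and the voom counts given beside counts of 0 were chosen after seeing the data. The comparison of resistant with parental HCC827 cells and its alternatives, its comparison with the treatments, and a control split of 2 and 2 were not run. With a library left out, the lone library of its group is assumed to vary like the others. The cause of the changes below was not tested. Genes named as largest rises or falls were followed through the settings that kept them. Of their values, 960 kept direction and side of the threshold, 87 came to pass it, 91 no longer passed and 0 reversed. Genes named only as list members, or only because they are always named, were not followed in this way. In set A the reference was the fit without a block, which called 0 genes. A set A value that stayed uncalled thus counts among the 960, which is no sign that its change is stable. For the most described lists the numbers in the same order were 654, 37, 23 and 6. Direction was compared only for lists called at first, so the 654 include lists that stayed uncalled whatever their direction. The 6 reversals are all of called lists.

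In set A limma and limma voom without a block called 0 genes in each comparison (255, 107 and 93 at an unadjusted p under 0.05 for magnolin, fraction and fraction against magnolin). The replicate block gave 130, 24 and 24, voom with the block 603, 74 and 126, and protein-coding genes with the block 577, 78 and 135. The block also changed list calls in set A of xenobiotic receptor targets, drug efflux and squamous genes with magnolin (adjusted p = 0.0341, 0.0341 and 0.0131 with the block). For the fraction it changed those of EGFR family, heat shock and leukocyte genes (0.0099, 0.0521 and 0.0169), and between the treatments those of EGFR family, alveolar, squamous and fibroblast genes (0.00345, 0.0431, 0.049 and 0.000926). In set B it changed those of NRF2 targets and mitochondrial transcripts with magnolin (0.0499 and 0.049) and of bypass receptors and class I genes between the treatments (0.0576 and 0.0516). Apart from these and those given with the results, the block changed no other list call.

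With an estimated correlation, camera called 0 lists in all 6 comparisons. Set A lists called for the fraction (8) were 4 with no filter, 14 with voom and the block, 14 with protein-coding genes and the block, and from 3 without fraction replicate 2 to 14 without control replicate 1. Between the treatments they (11) were 7 with no filter. Medians between the treatments in set A reversed for NF-kB genes at a mean FPKM of at least 5 (-0.09). With libraries left out they ranged from -0.09 without magnolin replicate 1 to 0.62 for NF-kB genes, from -0.09 to 0.77 for mitosis and -0.13 to 0.49 for S phase, both lowest without magnolin replicate 2, and from -0.49 to 0.01 without fraction replicate 1 for ATF4 targets, which were at 0 without magnolin replicate 2.

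In set B magnolin calls (92) were 0 with no filter (3021 at an unadjusted p under 0.05, 360 by voom), 218 at a mean FPKM of at least 5, 43 with the block, 578 with voom, 395 with protein-coding genes, 573 with voom and the block, 353 with protein-coding genes and the block and 165 with the 2 groups alone. They ranged from 0 without control or magnolin replicate 3 or 4 (1063 to 1484 at an unadjusted p under 0.05, 133 to 218 by voom) to 154 without fraction replicate 3, with 140 without fraction replicate 4. Fraction calls (2918) were 1598 with no filter, 728 without control replicate 4, 947 without control replicate 3 and at most 3174. Calls between the treatments (2188) were 752 with no filter, 1311 with the block, 3524 with voom, 3398 with voom and the block and 1034 with the 2 groups alone. They were 226 and 294 without magnolin replicates 4 and 3, 937 and 951 without control replicates 4 and 3, and at most 3017.

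The correlation of responses in set B (0.478) was 0.529 at a mean FPKM of at least 5, 0.565 with protein-coding genes with or without the block, 0.204 and 0.284 with 1 control each, and 0.405 to 0.559 without a library. In set A (0.648) it reversed to -0.373 and -0.271 with 1 control each, which by construction puts the difference between control replicates 1 and 2 into the responses with opposite sign. It was 0.357 without fraction replicate 1, 0.392 without fraction replicate 2, 0.404 without magnolin replicate 1 and at most 0.868. In joint fits voom gave 24, 235 and 13 genes. For the fraction (25) the set term gave 1, a pseudocount of 0.1 gave 65, and omissions ranged from 0 without replicate 3 or 4 (1242 and 1002 at an unadjusted p under 0.05, 20 and 12 by voom) to 107 without replicate 1. For magnolin limma gave 1 without replicate 2 and 0 without replicate 1, 3 or 4 (1039, 1055 and 986 at an unadjusted p under 0.05, 9, 6 and 8 by voom). Between the treatments it gave 0 without replicate 1, 2, 3 or 4 (888, 2333, 506 and 462 at an unadjusted p under 0.05, 0, 148, 0 and 0 by voom). Rescaling moved the median of all genes by at most 0.055. Depth limits genes of few reads.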

Other observations

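The lists and levels in this part were chosen after the results were seen; the test of short genes was set before its result was known, though simulated data had already tied false calls to such genes.

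With the fraction in set B, 4 of 8 drug efflux transporters rose, with 4 higher and 1 lower adjusted over the list alone (limma camera, median 0.36, adjusted p = 0.0229; adjusted p = 0.245 with an estimated correlation). ABCG2 rose from 18.8 ± 1.79 to 34.2 ± 3.43 FPKM (mean ± SD, n = 2) and ABCC3 from 13.4 ± 1.69 to 32.1 ± 2.79. Of 5 metallothioneins, a family of similar genes, 2 rose, also 2 adjusted over the list alone (median 0.48, adjusted p = 0.00988; adjusted p = 0.321 with an estimated correlation). MT2A rose from 184 ± 2.51 to 280 ± 34.5 FPKM. Of 13 FOXO targets 5 rose, 7 adjusted over the list alone (median 0.39, adjusted p = 0.00753; adjusted p = 0.308 with an estimated correlation). Between the treatments, 7 of 20 epithelial markers were higher and 2 lower with the fraction than with magnolin, 10 and 3 adjusted over the list alone (median 0.35, adjusted p = 0.0108; adjusted p = 0.262 with an estimated correlation).

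With magnolin in set B, ABCG2 rose from 18.8 ± 1.79 to 39.5 ± 2.15 FPKM, but did not pass with the replicate block (adjusted p = 0.0603). Cytosolic ribosomal protein genes were called higher as a list, with none of 30 passing over all genes or adjusted over the list alone (median 0.14, adjusted p = 2.54e-06; adjusted p = 0.444 with an estimated correlation). Of 14 class I antigen presentation genes, which include similar HLA genes, 1 fell, also 1 adjusted over the list alone (median -0.17, adjusted p = 0.00215; adjusted p = 0.362 with an estimated correlation). Of 7 squamous and basal markers 1 fell, 3 adjusted over the list alone (median -0.43, adjusted p = 0.00013; adjusted p = 0.132 with an estimated correlation).

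Parental HCC827 cells, normalized separately from NCI-H1975, had ERBB2 at 16.1 ± 0.787 FPKM (mean ± SD, n = 2), ERBB3 at 10.2 ± 0.815, MET at 130 ± 2.76 and AXL at 1.07 ± 0.109. The lung lineage genes NKX2-1 and NAPSA were at 52.0 and 55.9 FPKM and at 53.3 and 54.2 in the HCC827 libraries, against 1.61 to 9.06 and 0.104 to 0.446 in NCI-H1975. VIM, a mesenchymal filament gene, was at 2.53 and 4.01 FPKM in HCC827 and 107 to 210 in NCI-H1975. These levels were not tested.

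Among set A calls with the replicate block, 57 over the 3 comparisons were genes under 300 bases, with a median of 5.33 reads per library. Few reads are a candidate explanation for these calls. Limma voom with the same block called 5 of the 57, or 8.77%, against 105 of 121 longer ones, or 86.8%.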
